A study of Mus musculus with 12 samples.

How the data were processed

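RNA was sequenced in 12 libraries from mouse pre-B acute lymphoblastic leukemia cells, a malignancy of B-cell precursors. Per the labels, the cells come from C57BL/6J mice, lack p19 (the alternative-reading-frame product of Cdkn2a) and were transformed with the BCR-ABL1 fusion kinase. There are 4 groups of 3 libraries: Phf6 wild type (WT), cells with a short hairpin RNA against Phf6 (KD), and cells knocked out for Phf6 with either of 2 single guide RNAs (KO_sg1 and KO_sg4). Per the labels' protocols, cells were grown in RPMI-1640 with serum, RNA was prepared on RNeasy columns, and cDNA libraries were made with a TruSeq mRNA kit. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether the 3 libraries of a group came from separate cultures or separate transductions, so the p-values measure the spread between these libraries, which may be technical.

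The authors deposited one table of estimated counts for 23224 genes, named by symbol. Per the submitters' processing notes, reads were handled with Bowtie 1.0.1 and RSEM 1.2.12 on the mm9 mouse genome; the gene annotation, the strand setting and the read length are not given in the sources used here. RSEM shares reads that match several genes among them by their estimated abundance, so its counts need not be whole. Values of near-identical genes, such as the H2-Q genes, the Csf2rb pair, histone clusters and ribosomal protein genes with processed copies, are therefore uncertain, as are those of overlapping and antisense genes. Library totals ran from 20382328 to 36032369 estimated counts. A count of 0 in 1 library allows a level of up to 0.0833 to 0.147 CPM (counts scaled to a common library total), taking 3 counts as the floor; floors and intervals cover counting error only.

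The deposited estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with the groups as design and a minimum count of 10, which left 12335 genes. Libraries were scaled with TMM factors (0.88 to 1.14), and CPM values of single genes are TMM-scaled unless named as shares of the library total. Each comparison was a contrast in one edgeR quasi-likelihood model of all 12 libraries with 4 group means, so that all comparisons share one estimate of the spread (common biological coefficient of variation 0.0768). The KO contrast gives both guides equal weight. Tests were two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p below 0.05. Values after ± are standard errors for log2 fold changes and SDs over libraries for CPM. Replicate numbers were not used as a block: over the 18 pairs of libraries that share a number, the correlation of deviations from group means ran from -0.238 to 0.101.

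Before the data were examined, 29 gene lists were fixed: B-cell transcription factors, B-cell surface and receptor signalling, mature and activated B cell, V(D)J recombination, MHC class II, T-cell identity, Notch pathway, NK and innate lymphoid cell, myeloid cell, erythroid and megakaryocyte, stem and progenitor cell, stromal and epithelial cell, nucleolus and RNA polymerase I, the NuRD complex, cytosolic ribosomal proteins, p53 targets, cell cycle, interferon-stimulated, glycolysis, cholesterol synthesis, integrated stress and unfolded protein response, JAK-STAT targets, immediate early genes, adhesion and homing, cytokine receptors of lymphoid precursors, replication-dependent histones, mitochondrially encoded genes, sex-linked checks and genotype checks. No mitochondrially encoded gene was analysed here. Lists with at least 5 tested members were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Fry tests whether the members move, on balance, one way, and does not compare them with other genes.

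The rule for named genes was also fixed before the data were examined. It takes the 12 highest and 12 lowest genes of KO against WT with both guides called the same way, the 8 highest and 8 lowest of KD against WT, and the 5 highest and 5 lowest between the guides, each with a mean of at least 5 CPM in a group compared. It adds up to 3 called members per list with the largest absolute change, and a fixed set of lymphoid genes around Phf6. Gene models without a standard symbol are skipped. Some genes that the rule names are not reported here. Genes at 0 counts in one group are given as "at least" a fold, against a floor of 3 counts over the group, and genes at 1 to 3 counts as a ratio with its 95% counting interval (exact binomial).

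For checks on gene properties, 22795 of the 23224 symbols were matched to GENCODE mouse annotation of GRCm38, used for chromosome names, GC content, length and coding sequence only; no coordinates are given, since that build is not the one of the counts. A hydrophobic segment was called where the most hydrophobic stretch of 19 residues of the coded protein had a mean Kyte-Doolittle hydropathy of at least 1.9, and no segment where it lay below 1.3. This is a sequence rule for signal peptides and membrane-spanning segments, not an annotation of the protein's place. It was added after a shift of membrane-protein transcripts had been seen in the KD libraries. A trend on this hydropathy, or on GC content and length, was removed per library by loess through offsets.

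The tests were tried on simulated counts drawn from the real means and library sizes with 50 genes changed at each fold. For KD against WT, over 12333 genes, 42% were recovered at 1.25-fold, 72% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, and 5 of 12133 unchanged genes were called. For KO against WT the recovered shares were 38%, 82%, 96% and 100%, with 10 unchanged genes called. With a hydropathy trend simulated over 12334 genes for KD against WT, 4509 of 12134 unchanged genes were called before and 12 after its removal. That trend was linear and the same for all genes of equal hydropathy. In the real KD libraries the removal left a difference of 0.185 between the medians of genes with and without a segment. The 12 calls are therefore not the error rate of the real removal.

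Overlaps between comparisons that share the WT libraries were set beside 20 simulations of unchanged groups against the same controls. Alternatives planned beforehand were DESeq2 and upper-quartile scaling, 2 other filters on low counts, the DESeq2 Wald test, limma-voom, a replicate block, fits of only the groups compared, unrounded counts, stricter thresholds, and leaving out each library in turn. Alternatives added after the data had been seen were leaving out Rn45s and Lars2 (which draw ribosomal RNA reads), library totals alone, GC and length trends removed, the hydropathy trend removed, only genes with no segment, and Y-linked genes left out. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9.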

Results

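Transcript levels were measured by RNA-seq in mouse pre-B acute lymphoblastic leukemia cells driven by BCR-ABL1, with Phf6 intact (WT), lowered by a short hairpin RNA (KD), or knocked out with 1 of 2 guide RNAs (KO_sg1 and KO_sg4). Each of the 4 groups had 3 libraries. The series asks whether PHF6, an X-linked chromatin protein with PHD-like zinc fingers that is lost in some leukemias, maintains B-cell identity. Estimated counts summed to 26286540 to 30580071 in the WT libraries, 23179952 to 28524657 in KD, 20382328 to 36032369 in KO_sg1 and 21885578 to 30502951 in KO_sg4, and 12335 genes were tested. Replicate libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom from 3.38 to 64.1 over the 12 pairs, so no pair looked like 1 library deposited again under another name. This does not show that replicates came from separate cultures, and the spread between them may be technical. In a principal component analysis, component 1 held 61.8% of the variance, with KD libraries at -85.9 to -84.9, WT at -17.0 to -14.9 and KO at 45.9 to 52.8.

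Phf6, the targeted gene, stood at 34.5 ± 0.751 CPM in WT (SD, n = 3). It was 8.79 ± 0.429 CPM in KD, a log2 fold change of -1.97 ± 0.12 (edgeR adjusted p = 2.32e-09), and 3.40 ± 0.288 CPM in KO_sg1. In KO_sg4 it was 36.6 ± 7.37 CPM, with library values of 44.3, 29.5 and 36.1, and did not pass the test against WT (log2 fold change 0.09). Without KO_sg4 replicate 2 that value was 0.22 and passed the test (adjusted p = 0.0321), and without KO_sg4 replicate 1 it was -0.06. A guide-directed small insertion or deletion need not lower the mRNA of its gene, so Phf6 mRNA does not check the label of KO_sg4. Cdkn2a, the locus that encodes p19, gave 80.5 CPM in WT and fell in KO (log2 fold change -0.43 ± 0.10, adjusted p = 0.00352) and in KD (-1.24 ± 0.12, adjusted p = 3.99e-07). Of the 5 genotype check genes, 2 fell and none rose in KO (list adjusted p = 0.234; for KO_sg1 alone adjusted p = 0.0446, or adjusted p = 0.215 with an estimated correlation, and for KO_sg4 alone 0.921), and 1 rose and 2 fell in KD (0.551), where the list's median was 0.13, its mean -0.25 and its test downward. The KO_sg1 call of this list was lost without WT replicate 3, KO_sg1 replicate 2 or KO_sg4 replicate 3 (adjusted p = 0.051, 0.0578 and 0.0567).

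The Y-linked genes Ddx3y, Kdm5d and Uty separated KO from the other groups. Summed as shares of the library total, they gave 74.7 to 85.9 CPM in the WT libraries, 113 to 120 in KD and 0.0328 to 0.137 in the 6 KO libraries, from 1 to 4 counts each. Xist, the RNA of the inactive X chromosome, was at 0.151 to 0.982 CPM in all 12 libraries. Of the 4 sex-linked check genes tested, 3 fell in KO, with a median log2 fold change of -8.84 when genes near 0 stand at their bound, and 2 rose in KD. Kdm5d, at 0 counts in KO, was at least 1330-fold lower than in WT, and Ddx3y, at 3 counts, was lower by a ratio of 2380 (95% counting interval 815 to 11600).

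**Figure D1:**
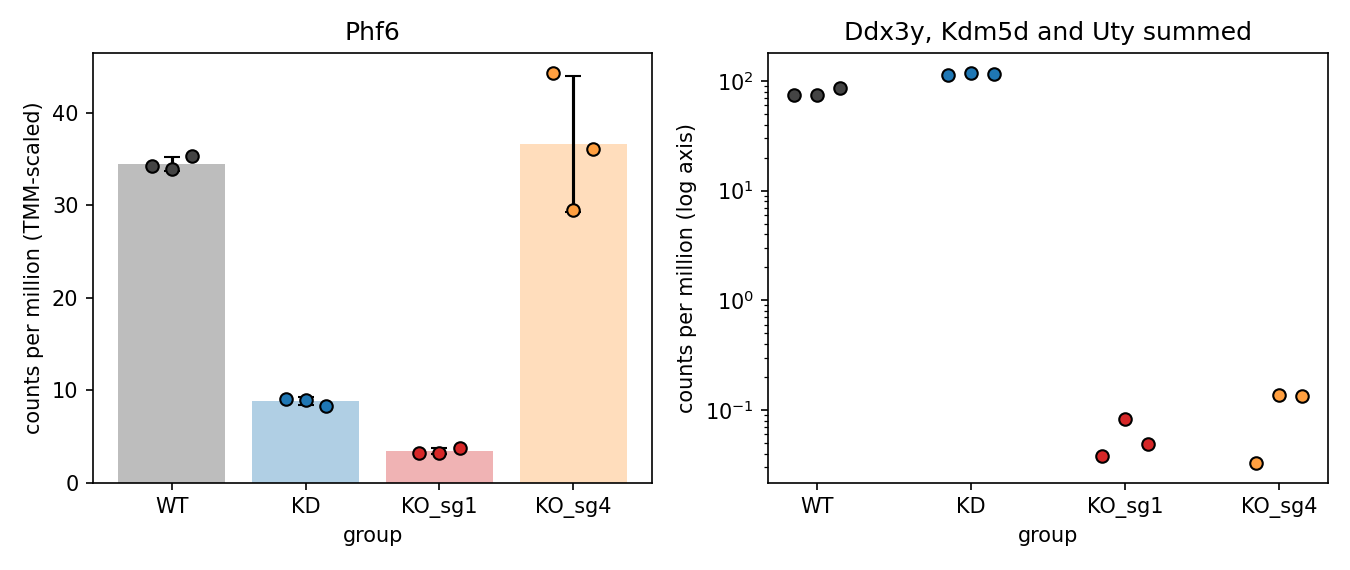
Left, Phf6 in TMM-scaled CPM for each of the 12 libraries (points) with the group mean (bar) and SD (whisker, n = 3); KO_sg4 averages 36.6 against 34.5 in WT. Right, the summed CPM of Ddx3y, Kdm5d and Uty, as shares of the library total on a log axis; the 6 KO libraries lie between 0.0328 and 0.137 and the others between 74.7 and 120.

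The libraries labelled as Phf6 knockouts were compared with wild type to find the genes that differ between them; for KO_sg4 the loss of PHF6 rests on the label. Antigen presentation, adhesion and cytokine-signalling transcripts fell in the KO cells, while enzymes of cholesterol synthesis rose. Cd74, the invariant chain of MHC class II, fell from 248 ± 14.7 CPM in WT to 9.80 ± 0.127 in KO_sg1 and 13.4 ± 1.42 in KO_sg4. Igf1, insulin-like growth factor 1, rose from 3.82 ± 0.484 CPM to 42.5 ± 0.263 and 28.3 ± 0.655. In all, 5120 genes changed, 2189 higher and 2931 lower, and among the 1204 that changed at least 2-fold 994 were lower and 210 higher.

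The 12 genes that rose most in KO included Scn4b, a sodium channel subunit (log2 fold change 5.60 ± 0.16, adjusted p = 2.66e-12), and the signalling adaptor Grap2 (5.56 ± 0.19, 1.56e-11). The calcium channel gene Cacna1h rose by 5.53 ± 0.25 on that scale, the phagocytic receptor gene Megf10 by 4.53 ± 0.17 and the adenylate cyclase gene Adcy6 by 3.31 ± 0.14. Car2, a carbonic anhydrase, went from 48.0 ± 0.252 CPM to 288 ± 2.00 in KO_sg1 and 216 ± 11.6 in KO_sg4. Klhdc2, a substrate receptor of a ubiquitin ligase, went from 17.9 CPM to 97.1 and 108. H2-Q7, a class I-like gene with close copies, rose too (2.98 ± 0.40, 3.27e-05), although WT libraries themselves ran from 0.117 to 2.71 CPM.

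Among the 12 lowest were genes that were nearly silent in both guides. Ly86, which encodes the MD-1 partner of the B-cell surface protein RP105, had 0 counts in all 6 KO libraries against 27.2 ± 0.415 CPM in WT, at least 1440-fold lower, and stood at 21.1 CPM in KD. Rap1gap2, a GTPase activator of Rap1, fell from 54.9 ± 1.03 CPM to 0.00983 in KO_sg1 and 0.189 in KO_sg4, and the olfactomedin gene Olfm1 from 44.2 ± 0.868 CPM to 0.0186 and 0.523. The calcium-binding protein gene S100a4 fell by 7.83 ± 0.14 on the log2 scale (adjusted p = 2.29e-14) and the purine enzyme gene Gmpr by 8.11 ± 0.20 (4.61e-13). Itgb3, the integrin beta 3 chain, fell from 109 ± 1.3 CPM to 1.51 in KO_sg1 and 0.123 in KO_sg4. At 1 or 2 counts over the 6 KO libraries, Stc2 was lower by a ratio of 1380 (247 to 54600), Bahcc1 by 1390 (248 to 54900) and the receptor kinase gene Axl by 399 (110 to 3300).

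The MHC class II list fell in KO: 7 of its 10 genes were lower and 1 higher (median log2 fold change -2.86, camera adjusted p = 7.47e-14, adjusted p = 0.0314 with an estimated correlation). H2-Aa fell by 4.41 ± 0.14 on the log2 scale and H2-Eb1 by 4.12 ± 0.20. H2-Ob, a chain of the peptide-exchange modulator, rose (0.43 ± 0.07, 0.00017). Of the 14 myeloid genes tested, 11 fell and none rose (median -2.78, adjusted p = 6.55e-08), with Fcgr1, the high-affinity IgG receptor, down by 6.75 ± 0.13 and Csf1r, the receptor of macrophage colony-stimulating factor, by 5.14 ± 0.42. That call was lost with an estimated correlation (adjusted p = 0.061). WT expressed 9 of these myeloid genes at 1 CPM or more. Of 5 stem and progenitor genes tested, 4 fell and 1 rose (adjusted p = 0.00139; adjusted p = 0.0314 with an estimated correlation), with Lmo2 at -1.69 ± 0.05 and Flt3 at -2.83 ± 0.55.

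Adhesion and homing genes fell, 11 of 14 against 1 higher (median -0.59, adjusted p = 2.94e-11, adjusted p = 0.00197 with an estimated correlation). Itgal, the LFA-1 alpha chain, changed by -2.90 ± 0.07. With the hydropathy trend removed, 10 adhesion genes were lower and 1 higher (median -0.385), and the list was still called (camera adjusted p = 1.7e-08). The cytokine receptor list had 6 of 10 genes lower and 1 higher (adjusted p = 0.0018, or adjusted p = 0.0314 with an estimated correlation). Csf2rb2 was at -2.03 ± 0.10 and Ifngr1 at -1.11 ± 0.04. Il7r was at 0.89 ± 0.07 in the mean of both guides, but the guides differed for this gene. With the hydropathy trend removed the list was still called in that mean (camera adjusted p = 0.0255). In KO_sg4 alone its call was lost (adjusted p = 0.0141 before and 0.0796 after). JAK-STAT targets fell, 11 of 14 with none higher (median -0.93, adjusted p = 2.46e-08, adjusted p = 0.00313 with an estimated correlation), with the feedback inhibitors Socs3 at -1.78 ± 0.05 and Cish at -1.65 ± 0.07. Immediate early genes had 8 of 15 lower and 3 higher (adjusted p = 0.0403), among the lower Klf2 (-2.61 ± 0.07) and Fos (-2.18 ± 0.17). That call was lost with an estimated correlation (adjusted p = 0.121) and without KO_sg4 replicate 1 (0.0651), and the list was not called for KO_sg1 alone (0.168; between the guides 0.271).

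Cholesterol synthesis genes rose, 17 of 18 with none lower (median 0.62, adjusted p = 6.93e-12, adjusted p = 0.0266 with an estimated correlation). Lss, lanosterol synthase, rose by 1.09 ± 0.04 and Idi1, isopentenyl diphosphate isomerase, by 1.06 ± 0.07. All 17 glycolysis genes fell in the mean of both guides (median -0.34, adjusted p = 2.08e-06, or adjusted p = 0.121 with an estimated correlation), led by Hk1, a hexokinase, from 46.5 ± 1.24 CPM to 5.86 ± 1.02 in KO_sg1 and 2.74 ± 0.406 in KO_sg4. The list was called for each guide (camera adjusted p = 9.53e-05 for KO_sg1 and 4.85e-07 for KO_sg4) and not between them (0.138). With the hydropathy trend removed, 11 were lower and 1 higher in KO_sg1, and 17 lower in KO_sg4. In the integrated stress and unfolded protein list, 10 of 16 fell and 5 rose (adjusted p = 1.54e-05; adjusted p = 0.121 with an estimated correlation). Atf3 (-3.51 ± 0.08) and Trib3 (-1.40 ± 0.05), both induced by amino acid stress, were lower, and the chaperone gene Hspa5 was higher (0.49 ± 0.05).

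The B-lineage lists were mixed in KO. Of 22 B-cell surface and receptor signalling genes, 11 fell and 5 rose (median -0.14, adjusted p = 0.0347; adjusted p = 0.242 with an estimated correlation). The call was also lost with the hydropathy trend removed (adjusted p = 0.0848), and the list was not called between the guides (0.872). Blk, a Src-family kinase of B cells, fell from 39.0 ± 1.97 CPM to 0.807 ± 0.25 and 3.51 ± 0.517, and Bank1, a B-cell scaffold, by 1.62 ± 0.08 on the log2 scale. The surrogate light chain genes Igll1 (-0.41 ± 0.06) and Vpreb1 (-0.33 ± 0.09) fell, the latter not without WT replicate 2 (adjusted p = 0.0555) and not in KO_sg1 alone (-0.15, adjusted p = 0.297; between the guides 0.0239). Of 19 B-cell transcription factors, 9 rose and 7 fell, and the list was not called (adjusted p = 0.148). Lef1 (1.24 ± 0.11) and Id3 (1.18 ± 0.07) were higher, Ikzf1, encoding Ikaros, was lower (-0.44 ± 0.07), Pax5 was at 0.40 ± 0.15 (adjusted p = 0.0386) and Ebf1 at 0.07 ± 0.08 (0.496). The Pax5 call was lost without any 1 of WT replicate 1, 2 or 3 (adjusted p = 0.0993, 0.069 and 0.12) or KO_sg1 replicate 1 or 3 (0.0708 and 0.0779), by limma-voom (0.0531) and with only the groups compared in the fit (0.0659). Pax5 was not called in KO_sg4 alone (0.29, adjusted p = 0.191; between the guides 0.302). Of 11 mature and activated B-cell genes, 5 rose and 3 fell (adjusted p = 0.498), with a median of 0.18, a mean of -0.14 and a test direction upward.

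Of 12 recombination and end-joining genes 6 rose and none fell in the mean of both guides (adjusted p = 0.143), while 4 rose and 2 fell in KO_sg1 and 5 rose and 3 fell in KO_sg4. Dntt, terminal transferase, rose with each guide (2.12 and 2.22) at low levels, from 0.31 CPM in WT to 1.36 in KO_sg1 and 1.45 in KO_sg4. Rag1 fell in KO_sg1 (-0.86, adjusted p = 1.70e-04) and rose in KO_sg4 (1.65), and Rag2 likewise (-0.50 and 1.46). The mean of Rag1 over the guides (0.39 ± 0.11, adjusted p = 0.0116) was not called without WT replicate 1 or WT replicate 2 (adjusted p = 0.0506 and 0.0534). Of 16 T-cell markers tested 3 rose and 4 fell in the mean of both guides (adjusted p = 0.576), with a median of -0.11, a mean of -0.32 and a test direction upward. In KO_sg1 5 were higher and 3 lower, and the list was called upward (adjusted p = 0.0489; adjusted p = 0.144 with an estimated correlation). That call was lost without any 1 of WT replicate 1, 2 or 3, KO_sg1 replicate 2 or KO_sg4 replicate 2 (adjusted p = 0.0595, 0.0513, 0.0671, 0.0511 and 0.0651). In KO_sg4 2 were higher and 6 lower (adjusted p = 0.585). Lck, a proximal T-cell receptor kinase, rose (1.79 ± 0.06) and Cd28 fell (-3.18 ± 0.18). Cd4, Cd3e and Bcl11b did not pass the filter, with group means of at most 0.0642 CPM, and Gata3 was at -0.39 ± 0.40 (0.47). The Notch pathway had 4 of 16 higher and 7 lower (adjusted p = 0.148), with Jag2 at -5.09 ± 0.14 and Hes5 at 2.12 ± 0.15. Of 3 NK-cell genes tested, 2 rose and 1 fell. Klrd1, one of the higher genes, rose in KO_sg4 (2.13) and was at 0.24 in KO_sg1 (adjusted p = 0.272).

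PHF6 is found in the nucleolus and binds the NuRD remodelling complex. Nucleolus and RNA polymerase I genes were higher in 12 of 23 and lower in 1, by small amounts (median 0.17, adjusted p = 0.01; adjusted p = 0.192 with an estimated correlation), Nop58 by 0.39 ± 0.04. Of 13 NuRD genes, 4 rose and 2 fell (adjusted p = 0.498). Mta3, one of the lower genes, fell from 26.5 to 5.33 CPM in KO_sg4 (-2.32) and was at -0.05 in KO_sg1 (adjusted p = 0.55). Among 78 ribosomal protein genes 5 rose and 1 fell (median 0.10, adjusted p = 0.0464), and among 58 histone genes 6 rose and none fell (median 0.55, adjusted p = 0.0365). Both calls were lost with an estimated correlation (adjusted p = 0.754 and adjusted p = 0.649) and with the hydropathy trend removed (0.137 and 0.0848). The ribosomal call in the mean of both guides was also lost without KO_sg1 replicate 3, KO_sg4 replicate 2 or 3, or WT replicate 3 (adjusted p = 0.083, 0.123, 0.0765 and 0.119). The histone call in that mean was lost without KO_sg1 replicate 3, KO_sg4 replicate 1 or 2, or WT replicate 2 (adjusted p = 0.059, 0.0641, 0.0805 and 0.109). By guide, 13 ribosomal genes were higher and 1 lower in KO_sg1 (adjusted p = 0.00128), against 1 higher and 1 lower in KO_sg4 (0.585, or 0.024 without KO_sg4 replicate 1), and 8 histone genes were higher in KO_sg1 (0.00476), against none higher and 1 lower in KO_sg4 (0.226). The KO_sg1 calls were lost with an estimated correlation (adjusted p = 0.637 and adjusted p = 0.602), and the histone list was not called between the guides (0.138). Histone mRNAs lack poly(A) tails. Rpph1, which is not polyadenylated either, was at 234.2 to 356 CPM in the KO_sg1 libraries, 112.3 to 221.3 in KO_sg4 and 130.5 to 146.3 in WT. Rn45s took 3.57 to 6.4% of the counts in KO_sg1, 1.22 to 4.36% in KO_sg4 and 0.915 to 3.94% in WT. Whether the histone counts follow the share of such RNA in a library was not tested. Cell cycle genes were higher in 11 of 25 and lower in 2 (adjusted p = 0.0901), p53 targets higher in 4 of 16 and lower in 8 (0.0898), interferon-stimulated genes higher in 1 of 15 and lower in 7 (0.498), erythroid and megakaryocyte genes lower in 1 of 5 (0.873), and stromal and epithelial genes lower in 4 of 5 (0.0583). The stromal list was called without KD replicate 1, 2 or 3 (adjusted p = 0.0432, 0.0425 and 0.0447) or WT replicate 2 or 3 (0.043 and 0.0479).

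Adjusted over the list alone, the KO counts were the same for all lists but 5: nucleolus (14 higher, 2 lower), ribosomal proteins (1 higher), immediate early genes (4 higher, 8 lower), cytokine receptors (1 higher, 7 lower) and histones (none). The KO libraries differ from WT in their Y-linked transcripts as well as in their Phf6 label, and Phf6 mRNA was called lower in KO_sg1 but not in KO_sg4. Every KO gene group here therefore moves together with the Y-linked difference. The share of calls that were higher, 42.8%, was 50.4% with DESeq2 size factors and 37.6% with library totals, so the excess of lower calls depends on the scaling, while the median of all genes moved by less than 0.1.

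The knockdown was compared with WT to find what differs when Phf6 mRNA is lowered. More genes changed than in KO: 9566 of 12335, 4583 higher and 4983 lower, with 2333 at least 2-fold higher and 966 at least 2-fold lower. Transcripts of proteins with a predicted hydrophobic segment, as membrane and secreted proteins have, were mostly higher, and those of proteins with no segment were lower in the median, with exceptions in both classes. Of 2545 genes with a predicted hydrophobic segment, 1966 rose and 196 fell (median log2 fold change 1.12), and of 5432 genes with no segment 1029 rose and 3154 fell (median -0.39). Of 3537 genes in neither class 1180 rose and 1489 fell (median -0.06). Per library, the class difference against the WT mean was 1.47 ± 0.026 in KD (SD, n = 3), -0.123 ± 0.013 in KO_sg1 and -0.127 ± 0.03 in KO_sg4, and WT libraries ranged from -0.008 to 0.011.

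**Figure D2:**
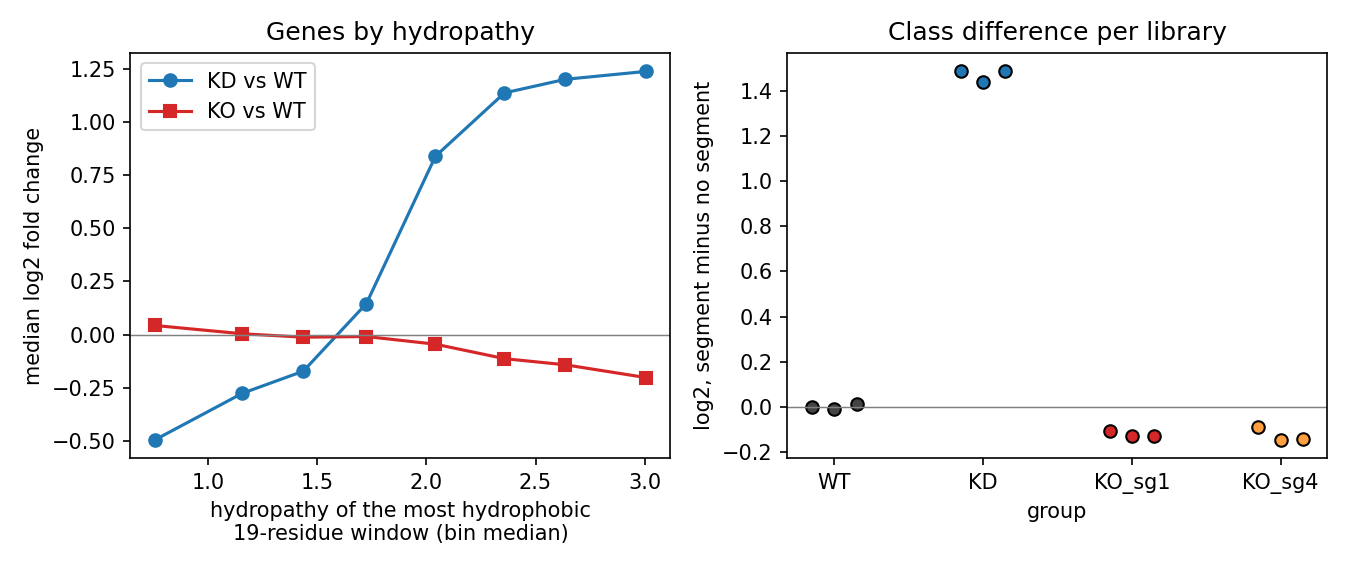
Left, median log2 fold change of tested genes in 8 bins of the hydropathy of the most hydrophobic 19-residue stretch of the coded protein, for KD against WT (circles) and KO against WT (squares); the KD median goes from -0.49 in the lowest bin to 1.24 in the highest. Right, for each of the 12 libraries, the log2 difference between the class with a hydrophobic segment and the class without, relative to the WT mean; the 3 KD libraries lie between 1.44 and 1.49.

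Other facts about the RNA moved with KD. Rpph1, the RNA component of RNase P, which is not polyadenylated, fell from 138 ± 8.02 CPM to 2.46 ± 0.687 (log2 fold change -5.78 ± 0.28, adjusted p = 3.34e-10). Of 58 replication-dependent histone genes, 33 fell and 2 rose (median -1.38, list adjusted p = 0.226, or 0.0403 without WT replicate 2). The 10 most abundant genes took 4.62 to 5.29% of the counts in KD and 6.61 to 12.4% elsewhere. Rn45s took 0.665 to 1.28% in KD, a range that overlaps the 0.915 to 3.94% in WT. With library totals in place of TMM, the share of called genes that were higher went from 47.9% to 59.7% (50.2% with DESeq2 size factors) and the median of all genes from -0.01 to 0.21, so directions in KD are relative to the scaling. With the hydropathy trend removed, an alternative chosen after the data had been seen, 7345 of the 9566 calls kept their direction, 343 turned, and 1872 genes were at least 2-fold changed. The class difference in KD against WT went from 1.503 to 0.185, so the removal was not complete.

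The genes that rose most in KD were Thbs1, thrombospondin 1 (log2 fold change 6.33 ± 0.25, from 0.0713 to 6.09 CPM), the secreted protease inhibitor gene Slpi (3.99 ± 0.24), Try5, a trypsin gene (3.73 ± 0.29), and Crim1 (3.68 ± 0.15). The gap junction gene Gja1 rose by 3.45 ± 0.13 and the drug exporter gene Abcc1 by 3.34 ± 0.13. H2-Q7 (3.42 ± 0.42) rose in KD as it did in KO. Il4i1 (3.48 ± 0.49) was not called by the DESeq2 Wald test (adjusted p = 0.0643). With the hydropathy trend removed, Thbs1 stood at 6.59, Slpi at 3.57, Crim1 at 2.42, Gja1 at 2.28, Abcc1 at 2.14 and H2-Q7 at 2.33. Below Rpph1, the genes that fell most were Itgb3 (-4.56 ± 0.08), the immediate early factor gene Fosb (-3.39 ± 0.23), Stox2 (-2.69 ± 0.23), Shroom3 (-2.69 ± 0.16), Blk (-2.37 ± 0.12), Myl4 (-2.33 ± 0.13) and the lipid transfer gene Pctp (-2.25 ± 0.12). Itgb3 encodes a membrane protein and fell against the class shift; with the trend removed it stood at -5.69.

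Adhesion and homing genes rose in KD, 13 of 14 with none lower (median 1.32, adjusted p = 1.97e-10, adjusted p = 0.00963 with an estimated correlation). Itga6 rose by 2.39 ± 0.18 and Cxcr4 by 1.99 ± 0.08, or by 1.11 and 0.92 with the trend removed. All 14 have a hydrophobic segment, and with the hydropathy trend removed 6 were higher and 3 lower and the list was not called (adjusted p = 0.0558). Of 10 cytokine receptor genes, all with a segment, 8 rose and 2 fell (adjusted p = 6.41e-04, adjusted p = 0.0468 with an estimated correlation), Il7r by 1.98 ± 0.08 and Il2rg by 1.62 ± 0.05; with the trend removed these were 0.88 and 0.69, 4 were higher and 3 lower, and the list was not called and its test turned downward (adjusted p = 0.918). Myeloid genes rose in 12 of 14 and fell in 1 (adjusted p = 0.00183), Csf1r by 2.67 ± 0.22 and Fcer1g by 2.94 ± 0.13, and Notch pathway genes rose in 11 of 16 and fell in 2 (adjusted p = 0.0139), Notch1 by 1.51 ± 0.05 and Notch2 by 1.93 ± 0.11. Both calls were lost with an estimated correlation (adjusted p = 0.152 for each). With the trend removed Csf1r stood at 1.44, Fcer1g at 2.01, Notch1 at 0.44 and Notch2 at 0.62. The counts were then 9 higher and none lower for myeloid genes (adjusted p = 0.00363), and 9 higher and 2 lower for Notch, which was not called (0.249).

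B-cell surface and receptor signalling genes rose in 13 of 22 and fell in 8 (adjusted p = 0.0442; adjusted p = 0.35 with an estimated correlation), and the list was not called without KO_sg1 replicate 1 (0.0589) or with the hydropathy trend removed (0.616). Cd79b stood at a log2 fold change of 1.37 ± 0.07, and with the hydropathy trend removed at 0.13 ± 0.07 (adjusted p = 0.131). Cd79a stood at 1.41 ± 0.10 and, with the trend removed, at 0.59 ± 0.10, and Igll1 at 1.15 ± 0.07 and 0.43 ± 0.07. Vpreb1 rose by 1.16 ± 0.11, or 1.31 ± 0.11 with the trend removed. Mature and activated B-cell genes rose in 8 of 11 and fell in 1 (adjusted p = 0.00713; adjusted p = 0.204 with an estimated correlation), with Cd40 at 2.60 ± 0.33, Cr2, complement receptor 2, at 1.81 ± 0.08 and the plasma-cell marker gene Sdc1 at 1.64 ± 0.10. With the trend removed these 3 stood at 1.44, 0.83 and 0.52. Levels of Cd40 were low, at 0.343 to 0.665 CPM in the WT libraries and 2.26 to 3.13 in KD. A segment is predicted for 9 of the 11, and 7 were higher and 1 lower with the trend removed, without a call of the list (adjusted p = 0.174).

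Ribosomal, cell cycle, NuRD and nucleolus genes were lower in KD. Of 78 ribosomal protein genes 75 fell and none rose (median -0.88, adjusted p = 2.69e-08; adjusted p = 0.548 with an estimated correlation), Rpl5 by -1.19 ± 0.07. Cell cycle genes fell in 21 of 25 (adjusted p = 3.86e-05; adjusted p = 0.204 with an estimated correlation), Ccna2, cyclin A2, by -1.13 ± 0.07. NuRD genes fell in 11 of 13 and rose in 1 (adjusted p = 8.85e-04; adjusted p = 0.152 with an estimated correlation), Rbbp4 by -1.17 ± 0.06 and Hdac2 by -1.16 ± 0.05. Nucleolus genes fell in 15 of 23 and rose in 2 (adjusted p = 0.00247; adjusted p = 0.204 with an estimated correlation), with Npm1, nucleophosmin, at -1.32 ± 0.06. None of the ribosomal or cell cycle genes has a predicted segment, against 1 of the NuRD and 2 of the nucleolus genes. With the trend removed 67 ribosomal, 19 cell cycle, 11 NuRD and 14 nucleolus genes were lower, and the 4 lists were still called (adjusted p = 1.06e-04, 1.61e-04, 0.00363 and 0.0285). Their medians went from -0.88 to -0.48, -0.72 to -0.51, -0.75 to -0.58 and -0.50 to -0.29, and Rbbp4 to -0.74.

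B-cell transcription factors, none with a segment, fell in 11 of 19 and rose in 1, and the list was not called (adjusted p = 0.0588). It was called without WT replicate 2, KO_sg1 replicate 2, or KO_sg4 replicate 1 or 2 (adjusted p = 0.0406, 0.0493, 0.038 and 0.0384). Id3 (-1.19 ± 0.08), the coactivator gene Pou2af1 (-1.13 ± 0.06), Irf4 (-0.92 ± 0.10) and Ikzf1 (-0.88 ± 0.08) fell; Pax5 was at -0.32 ± 0.17 (0.0925). Pax5 was called lower in KD without KO_sg1 replicate 2 or KO_sg4 replicate 2 (adjusted p = 0.0456 and 0.0145), with only the groups compared in the fit (3.42e-06), with no filter on low counts (0.0246) and with the GC and length trend removed (0.0156), and stood at 0.13 with the hydropathy trend removed (0.477). Ebf1 was at 0.00 ± 0.09 (0.995). With the trend removed 4 factors were higher and 8 lower, Irf4 at -0.57. Recombination genes rose in 4 of 12 and fell in 6 (adjusted p = 0.594), Rag1 by 1.11 ± 0.12 and Xrcc4 by -1.34 ± 0.09. Both glycolysis and cholesterol synthesis divided within the list. Glycolysis genes fell in 15 of 17 (adjusted p = 0.00247; adjusted p = 0.35 with an estimated correlation), such as Tpi1 at -1.45 ± 0.08, while the membrane transporter genes Slc2a1 (1.57 ± 0.05) and Slc16a3 (2.22 ± 0.18) rose. Cholesterol synthesis genes rose in 12 of 18 and fell in 6 (adjusted p = 0.00212; adjusted p = 0.204 with an estimated correlation): Dhcr7 (1.53 ± 0.05) and Sqle (1.41 ± 0.08), enzymes of the endoplasmic reticulum membrane, rose, and the soluble enzyme gene Idi1 (-1.41 ± 0.08) fell. Of 10 enzymes of that membrane tested, 9 rose and 1, Lss, fell (-0.29 ± 0.05, adjusted p = 6.33e-05). With the trend removed Slc2a1 stood at 0.46, Slc16a3 at 1.23, Dhcr7 at 0.47, Sqle at 0.52 and Idi1 at -1.05. Then 15 glycolysis genes were still lower and the cholesterol list had 9 higher and 8 lower and was not called (adjusted p = 0.918).

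The remaining lists were not called in KD. MHC class II had 4 of 10 higher and 5 lower (adjusted p = 0.702; median -0.10, mean -0.12, test direction upward), with Cd74 at -0.33 ± 0.06, Ciita, the class II transactivator, at -2.41 ± 0.27 and H2-Ob at 1.36 ± 0.08. A segment is predicted for 7 of the 10, and with the trend removed Cd74 stood at -0.61 and H2-Ob at 0.20. Unfolded protein and stress genes had 7 of 16 higher and 7 lower (0.347; median -0.20, mean 0.19, test direction upward), with Hspa5 at 1.53 ± 0.06. T-cell genes had 5 of 16 higher and 4 lower (0.454), Cd5 at 2.15 ± 0.18, or 0.95 with the trend removed; JAK-STAT targets 6 of 14 higher and 7 lower (0.711); immediate early genes 3 of 15 higher and 7 lower (0.48); p53 targets 4 of 16 higher and 6 lower (0.747; median 0.04, mean -0.002, test direction downward); interferon-stimulated genes 7 of 15 higher and 3 lower (0.48). Stromal and epithelial genes had 4 of 5 higher and 1 lower (0.372), Krt18 being the lower (-4.73 ± 0.44); erythroid genes 1 of 5 higher (0.756; median -0.03, mean 0.28, test direction upward); progenitor genes 2 of 5 higher and 2 lower (0.635; median 0.21, mean 0.05, test direction downward). Of 3 NK-cell genes tested, 2 rose, among them Klrd1 (2.99 ± 0.14, or 1.9 with the trend removed), and 1 fell. Adjusted over the list alone, the KD counts were the same for all lists but adhesion (14 higher) and histones (2 higher, 31 lower).

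Each guide was also set against WT alone and against the other, to see whether both knockouts changed the same genes. KO_sg1 changed 4784 genes, 2082 higher and 2702 lower, and KO_sg4 changed 4929, 2215 higher and 2714 lower. Both guides changed 2922 genes the same way, against 968 expected for independent calls and 0.05 on average in simulated unchanged groups, and 193 genes in opposite directions. Their log2 fold changes correlated across genes at r = 0.685 (simulated 0.489), with a covariance of 0.843 (simulated 0.0251). Genes are not independent replicates. The simulated values argue against noise of the shared WT libraries as the source of most of the excess. A difference of the WT cells as a whole would not show in the simulations, and the 3 WT libraries cannot be split into 2 sets of at least 2. Both KO groups also lack Y-linked transcripts, so the agreement of the guides does not separate a loss of Phf6 from a shared origin. MHC class II, adhesion, JAK-STAT and cholesterol lists were called in the same direction for each guide, with adjusted p = 3.15e-11, 2.13e-09, 4.11e-06 and 3.01e-13 for KO_sg1 and 1.83e-11, 9.92e-10, 4.67e-09 and 7.80e-10 for KO_sg4. With an estimated correlation, MHC class II was not called for KO_sg4 (adjusted p = 0.0648). With library totals, the share of calls that were higher in KO_sg1 went from 43.52% to 30.04%, and with DESeq2 size factors to 52.58%.

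Between the guides 3359 genes differed, 1700 higher and 1659 lower in KO_sg4, and 771 of them at least 2-fold. Rag1, a subunit of the V(D)J recombinase, stood at 14.9 CPM in KO_sg1 (13.6 to 16 in the 3 libraries) and 85.1 ± 19.2 in KO_sg4, with 27.2 ± 1.85 in WT. Rag2 differed too (log2 fold change 1.96, adjusted p = 2.99e-08), as did Il7r (1.35, 1.71e-08). Tfpi, tissue factor pathway inhibitor, was at 0.547 ± 0.375 CPM in KO_sg1, 62.5 ± 3.60 in KO_sg4 and 54.0 ± 2.27 in WT, and the Wnt receptor gene Ryk at 0.0801, 27.5 and 4.19. Ano10 (6.98) and Zic2 (6.86) were also higher in KO_sg4, and Fam20c, at 1 count in KO_sg1, by a ratio of 571 (102 to 22600). Pak1, a kinase downstream of Rac, went the other way, at 10.9 CPM in KO_sg1 and 3 counts in KO_sg4, lower by a ratio of 304 (104 to 1470). Eid2 was lower by a ratio of 1060 (191 to 42100) and Marcks by 383 (106 to 3170), and Tes (-7.95) and Pcdhgc3 (-7.74) were lower in KO_sg4 as well.

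Of 26 lists tested between the guides 4 were called, all of them lost with an estimated correlation. T-cell genes were lower in KO_sg4 in 8 of 16 and higher in 1 (adjusted p = 8.45e-04; adjusted p = 0.0695 with an estimated correlation), among them Lck (-0.86), Cd5 (-2.37) and Tcf7 (-1.45). Stress genes were lower in 11 of 16 (adjusted p = 7.87e-06; adjusted p = 0.34 with an estimated correlation) and ribosomal protein genes in 5 of 78 (adjusted p = 0.00183; adjusted p = 0.924 with an estimated correlation), a call lost without KO_sg4 replicate 1 (0.119). The genotype checks, which hold Phf6 itself (3.45), were higher in 2 of 5 and lower in 1 (adjusted p = 0.0287; adjusted p = 0.398 with an estimated correlation), a call lost without KO_sg1 replicate 2 (0.0694). Without 1 library, JAK-STAT targets were called (KO_sg1 replicate 3 left out, adjusted p = 0.0335), as were histones (KO_sg4 replicate 2 left out, 0.00775). Adjusted over the list alone the counts were 2 higher and 8 lower, 13 lower, none, and 3 higher and 1 lower. The count of genes that differ rests in part on KO_sg4 replicate 2: without it 5329 genes were called. It also rests on the spread shared with the other groups: a fit of the KO libraries alone called 1595. With library totals the share of these calls that were higher in KO_sg4 went from 50.6% to 72.9% (44.9% with DESeq2 size factors) and the median of all genes from 0.01 to 0.13.

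Knockdown and knockout were set against each other to find which changes they share. KD and both guides changed 1083 genes the same way, 423 higher and 660 lower, against 0.05 in simulated unchanged groups. This is not above the 1143 expected if the KD calls were independent of the 1150 genes higher and 1772 lower with both guides, and 1288 of those genes went the opposite way in KD. Of the 1083, 61 were at least 2-fold higher and 82 at least 2-fold lower in all 3, where 23.5 and 51.8 are expected in the same way, and 212 genes changed at least 2-fold with both guides went at least 2-fold the opposite way in KD. Igf1, H2-Q7, Megf10, Grap2 and Pcdh11x were higher, and Itgb3, Gmpr, Blk, Stox2, Shroom3, Myl4 and Krt18 lower, by at least 2-fold in each. In KD, Megf10 (0.92) and Pcdh11x (0.82) were higher by less than 2-fold once the hydropathy trend was removed. Across all genes the changes of KD and KO were not aligned. Of 4117 genes called in both, 1834 went the same way, where 1997 are expected for independent calls, and 2283 in opposite directions, with r = -0.048 (simulated 0.58) and a covariance of -0.0454 (simulated 0.0251). With the hydropathy trend removed, 1119 genes changed the same way in all 3, where 1072 are expected, and KD and KO went the same way in 1869 genes and opposite ways in 2018. At 2-fold or more, 43 genes were then higher and 90 lower in all 3, where 14 and 29.7 are expected. Another 134 genes changed at least 2-fold with both guides went at least 2-fold the opposite way in KD. No expected count was worked out for opposite ways, with or without the trend. The excess of same-way genes at 2-fold therefore does not show that KD and KO agree in direction.

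KD and KO differed directly in 10270 genes, 5292 higher and 4978 lower in KD, and 4207 of them at least 2-fold. The calcium-regulating hormone gene Stc2 was 69.6 ± 3.73 CPM in KD against 8.68 ± 0.157 in WT and 1 count over the 6 KO libraries. Csf1r, Fcgr1 and Cd28 rose in KD (Cd28 by 1.62, or 0.52 with the hydropathy trend removed) and fell in KO, while Klhdc2, Car2, Lck and Id3 rose in KO and fell in KD. Lists called in opposite directions against WT differed in the direct test: adhesion and homing (adjusted p = 1.21e-17; adjusted p = 3.89e-04 with an estimated correlation) and cytokine receptors (adjusted p = 4.87e-06; adjusted p = 0.0144 with an estimated correlation), and also myeloid genes (4.03e-07), B-cell surface genes (0.00311), nucleolus (1.29e-04) and ribosomal proteins (2.39e-08), the last 4 not called with an estimated correlation (adjusted p = 0.161, 0.184, 0.161 and 0.517). With the hydropathy trend removed, the cytokine receptor and B-cell surface lists were not called between KD and KO (adjusted p = 0.298 and 0.0851), and against WT myeloid genes and nucleolus were the only 2 of the 6 lists still called in both KO (3.09e-08 and 0.0165) and KD (0.00363 and 0.0285). As given above, their calls against WT in the main fit were lost with an estimated correlation. Adjusted over the list alone, 14 of 14 adhesion genes and 8 of 10 cytokine receptor genes were higher in KD. The class with a hydrophobic segment had a median log2 fold change of 1.26 in this comparison and the class without one of -0.35. With library totals the share of calls that were higher in KD went from 51.5% to 62.7%, and the median of all genes from 0.05 to 0.29.

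**Figure D3:**
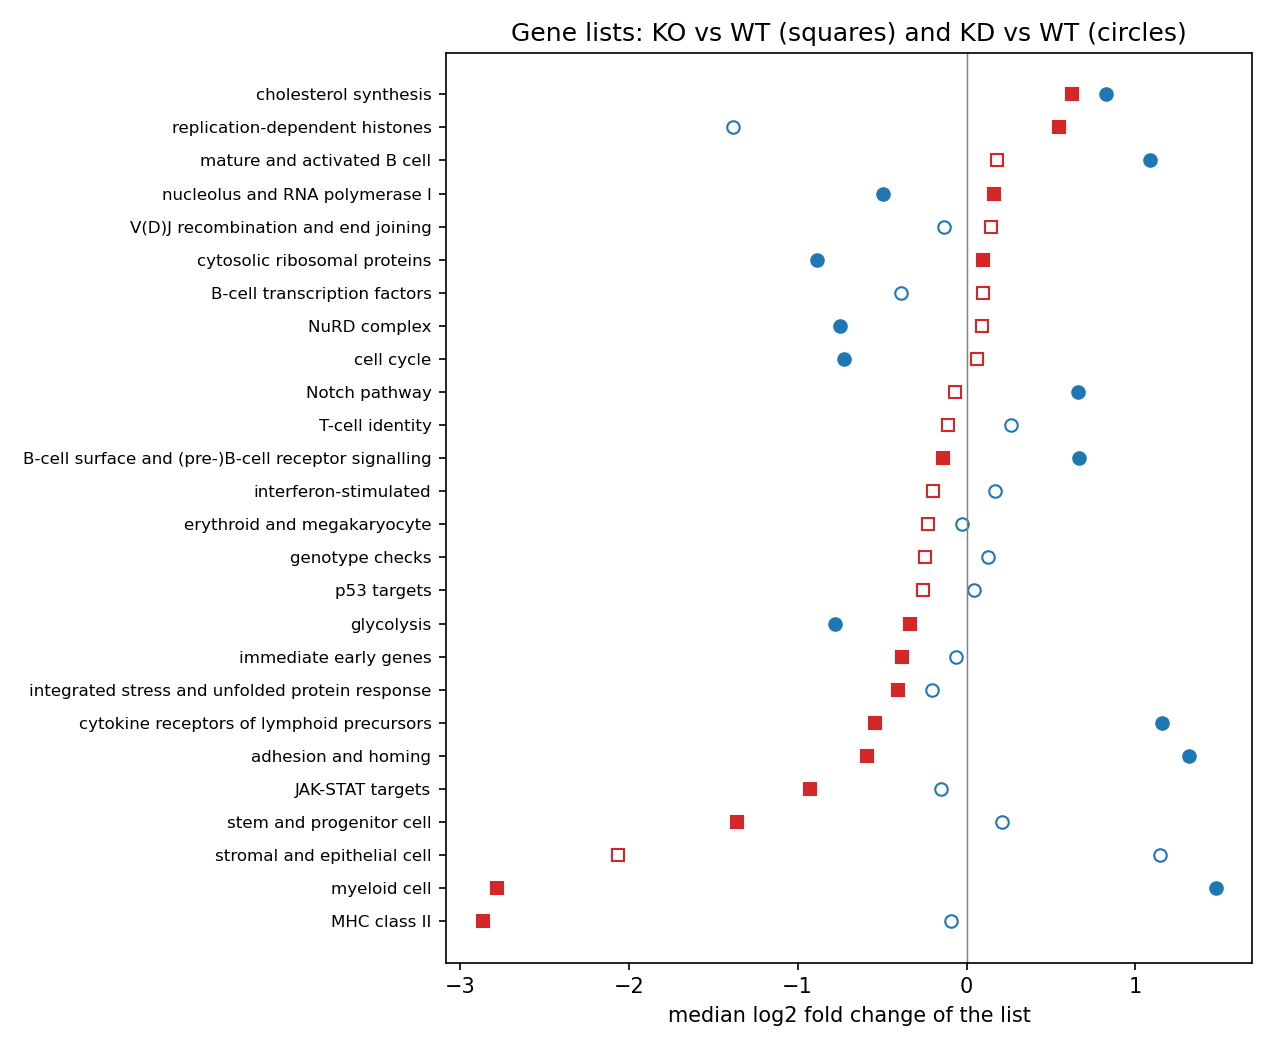
Median log2 fold change of the tested members of each of 26 gene lists in KO against WT (squares) and in KD against WT (circles); filled symbols are lists with a camera adjusted p below 0.05. Adhesion and homing lies at -0.59 in KO and 1.32 in KD, and cholesterol synthesis at 0.62 and 0.82.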

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

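The tests of mislabelling, depth and Xist for the Y-linked genes, of chromosome copy number and of the class shift as the whole of the difference for knockdown against knockout, and of the whole-class shift, its presence in the knockout and the carriers with the hydropathy trend removed for the class shift were chosen after the results were seen; the other tests, and the splits, were set before.

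The Y-linked genes were near 0 in all 6 KO libraries, which was not a question of the design. Mislabelling of a few libraries is excluded, since 6 of 6 KO libraries had Ddx3y, Kdm5d and Uty below 1 CPM in sum, and so is depth, since the WT share of these genes would give 1595 counts in the smallest KO library. Female cells that express Xist are excluded by Xist at 4 to 17 counts in each KO library, a KO to WT ratio of 1.04. Copy number change of other whole chromosomes shared by the guides is excluded by chromosome medians, Y left out, within 0.033 of the median of all genes. Such medians cannot show gains or losses of smaller segments, which stay untested. Both guides share the Y-linked pattern, so a hypothesis is that the KO lines descend from cells that had lost the Y chromosome, or come from other founder cells than WT and KD, and either may add differences to KO that are not due to Phf6. The design holds no Phf6-intact line without Y-linked transcripts, so that part stays untested.

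In KD, the median change of transcripts of proteins with a predicted hydrophobic segment lay above that of proteins with none, by 1.479 among genes outside the lists, so the shift is not limited to the listed genes, although 196 of the 2545 genes with a segment were lower and 1029 of the 5432 with none were higher. GC content and transcript length are excluded as the cause by a difference of 1.436 once their trends were removed. The KO libraries did not show this shift but a small difference the other way (-0.135), with library values from -0.147 to -0.092. Hydrophobicity as such is excluded as the whole cause by the mitochondrial carriers, made on free ribosomes, whose median lay at -1.16 relative to other solute carriers; with the hydropathy trend removed the medians were -0.237 and 0.297, a difference of -0.534 (permutation test over genes, 100000 resamples, two-sided p = 2e-05; genes are not independent replicates), so part of the -1.16 goes with the carriers' own hydropathy. A loss of cytosolic RNA before extraction, which would leave RNA bound to the endoplasmic reticulum or held in the nucleus, stays open: the median of the 3 nuclear transcripts tested was 0.828, above the bound of 0.5 written beforehand for that cause, with Neat1 (2.2 ± 0.10, adjusted p = 1.32e-10) and Kcnq1ot1 (0.83 ± 0.14, adjusted p = 1.09e-04) higher, but after Malat1 was seen at 0.09 ± 0.22 (adjusted p = 0.728) the rule was tightened to need every member called, so the test was not counted in its favour. Rpph1, the RNA component of RNase P, was not in the set written for this test and went the other way in KD (-5.78). It is not polyadenylated, so it does not settle the question. All 3 KD libraries carry the shift. A loss of cytosolic RNA, any other difference in the handling of the KD samples and a biological effect of the hairpin therefore cannot be told apart.

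KD and KO differed directly in 10270 genes, and 2283 genes called in both went in opposite directions against WT. GC and length trends are excluded as the cause, with 10555 genes called once they were removed. With Rn45s and Lars2 left out 10259 genes were called. Under the scaling farthest from TMM 4130 genes were at least 2-fold apart, against 4207 with TMM. The counts therefore hardly depend on those choices. These tests cannot exclude ribosomal RNA reads or scaling as a cause. Leaving out so few genes changes TMM little, and the scalings moved the median of all genes only from 0.048 to 0.291. With the hydropathy trend removed, 2961 genes were still at least 2-fold apart, so that trend is not the whole of the difference. The removal left a class difference of 0.178, from 1.604 before, so part of the class shift may remain in this count. KO against WT alone had 1179 genes at least 2-fold changed after the removal, so a large count was likely whatever the class shift did. Only 3 of the called genes lie on a chromosome with a shifted median, which is Y; this bound replaced an earlier one, a share of calls within 5 percentage points of that on other chromosomes, which was missed (-8.26) but rested on 4 Y-linked genes. The Y-linked difference and the open loss of cytosolic RNA both lie between these groups, and Phf6 mRNA does not show the loss of PHF6 in KO_sg4 (36.6 CPM against 34.5 in WT), so no share of the difference can be assigned to Phf6 dose.

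Of the lists called against WT in both KO and KD, 6 had opposite directions, and the direct tests of KD against KO gave adjusted p = 0.00311 for B-cell surface and receptor signalling, 4.03e-07 for myeloid genes, 1.29e-04 for nucleolus, 2.39e-08 for cytosolic ribosomal proteins, 1.21e-17 for adhesion and homing and 4.87e-06 for cytokine receptors. With an estimated correlation the first 4 were not called (adjusted p = 0.184, 0.161, 0.161 and 0.517), and with the hydropathy trend removed only myeloid genes (3.09e-08 in KO, 0.00363 in KD) and nucleolus (0.0165 and 0.0285) kept opposite calls against WT. In the main fit neither of these lists was called against WT with an estimated correlation, in KO or in KD. The other 4 lost a call: adhesion in KD (0.0558), cytokine receptors in KD (0.918) and against KO (0.298), ribosomal proteins in KO (0.137), and B-cell surface in KO (0.0848), KD (0.616) and KD against KO (0.0851). The guides differed in 3359 genes, and 193 genes were called against WT in both with opposite signs.

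Of the 84 splits of the 9 libraries into 6 and 3, 1 gave as many genes as KO against WT, the real one. It gave 2908 genes against at most 1175 in another split, which set the KO_sg4 libraries against the rest. For KD against KO it was again 1 of 84, with 9172 genes against at most 348 in another split, KO_sg1 against the rest. The split fits pooled the guides, so these counts are not the 5120 and 10270 genes of the main contrasts. They show that the counts go with the labelled grouping of these libraries. If the libraries of a group are technical repeats, the splits cannot exclude chance differences between the cell lines. The other comparisons allow 10 splits, too few for a share under 0.05. In each, 1 split gave as many genes, with real values of 10317 for KD, 5731 for KO_sg1, 3743 for KO_sg4 and 1595 between the guides, and 0 for the highest other split.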

How the results depend on the processing

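Library totals, removal of the hydropathy or GC and length trends, genes with no segment, and leaving out Rn45s and Lars2 or the Y-linked genes were chosen after the data had been seen. Of 4785 named-gene values under the settings chosen earlier, 4709 kept direction and side of the threshold, 59 lost and 4 gained the call and 13 turned; of 916 under the added ones the numbers were 896, 13, 1 and 6. Counts of changed genes moved most with the threshold, by construction. At 2-fold or more they were 1204 (KO), 3299 (KD), 1198 (KO_sg1), 1344 (KO_sg4), 771 (between guides), 4207 (KD against KO) and 143 (the same way in all 3), and at an adjusted p below 0.01 they were 1878 between guides and 690 in all 3. Fitting only the groups compared gave 1595 between guides and 3743 for KO_sg4, below the main counts. It gave 5731 for KO_sg1 and 10317 for KD, above them. The smaller number of samples alone therefore does not account for the 1595. KO_sg4 replicates were the least alike, with correlations of log CPM from 0.991 to 0.995, against 0.996 to 0.998 in the other groups. A spread shared with tighter groups may make the main counts for KO_sg4 and between guides too large. Whether it does was not tested. KD over genes with no segment gave 4008 (fewer genes tested).

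Leaving out 1 library at a time gave 4115 to 6440 genes for KO, 9125 to 10032 for KD, 3793 to 6080 for KO_sg1, 3993 to 5485 for KO_sg4, 2279 to 5329 between guides (the highest without KO_sg4 replicate 2), 9849 to 10655 for KD against KO and 818 to 1321 in all 3. Lists called ran from 12 to 15, 11 to 14, 12 to 15, 11 to 15, 3 to 5 and 13 to 15 in the first 6. Phf6 ran from -1.703 to -1.564 in KO, -1.997 to -1.902 in KD, -3.408 to -3.315 in KO_sg1 and -0.061 (without KO_sg4 replicate 1) to 0.225 (without KO_sg4 replicate 2) in KO_sg4.

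The replicate numbers do not pair the libraries: same-numbered deviations correlated at -0.238 to 0.101, and 3 of 12 libraries matched their own number best. With the replicate block the counts were 4642, 9345, 4264, 4423, 2730, 10108 and 936 in the same order, and it ended the calls of Hist1h2ac (adjusted p = 0.0532), Pax5 (0.0627) and Cd79a (0.0738) in KO, turned Ebf1 in KD and made 1 list call, mature and activated B cell in KD against KO (0.0489). It changed no other call of a named gene or list.

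With an estimated correlation 6, 2, 6, 3, 0 and 2 lists were called in KO, KD, KO_sg1, KO_sg4, between guides and KD against KO, from 14, 12, 14, 12, 4 and 14; fry, which asks another question, called 25 in KD, 20 in KO_sg4, 11 between guides and 23 in KD against KO. With the hydropathy trend removed 6 were called in KD.

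The cause was not tested for the values that changed direction. Ebf1 in KD stood at 0.044 with DESeq2 size factors and with the DESeq2 Wald test, 0.092 with upper-quartile factors, 0.05 with the 1 CPM filter, 0.002 with the block, 0.033 with only the groups compared, 0.058 without Rn45s and Lars2, 0.22 with library totals and 0.164 with the hydropathy trend removed, and from -0.054 to 0.062 with 1 library left out. Gata3 in KD was -0.017 with GC and length removed and ran from -0.241 (without WT replicate 2) to 0.495 (without WT replicate 1). With the hydropathy trend removed Bst2 was -0.048 and Pax5 0.126 in KD. List directions turned, with these adjusted p: with fry, T-cell in KO (0.762), ribosomal in KO_sg4 (0.844) and genotype checks in KD against KO (0.266); with the hydropathy trend removed, in KD MHC class II (0.249), p53, JAK-STAT and immediate early (0.99 each) and cytokine receptors (0.918), and in KD against KO T-cell (0.744) and genotype checks (0.872). With 1 library left out, adjusted p of lists that changed direction ran from 0.024 (without KO_sg4 replicate 1, where the list was called) to 0.907 for ribosomal proteins, 0.762 to 0.986 for interferon-stimulated genes and 0.582 to 0.986 for genotype checks in KO_sg4, from 0.834 to 0.99 for erythroid genes, 0.782 to 0.975 for nucleolus and 0.802 to 0.999 for NuRD between guides, and from 0.851 to 0.996 for genotype checks in KD against KO. Depth limits calls for genes near the floor of 3 counts.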

Other observations

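The criteria for silent genes and the genes named here were chosen after the data had been seen. Of 9258 genes with a mean of at least 5 CPM in WT, 12 were below 0.2 CPM in each of the 6 KO libraries, where 0.06 is expected if the guides were independent. Below it were 20 in KO_sg1, 27 in KO_sg4 and 1 in KD. Besides the Y-linked Ddx3y, Kdm5d and Uty the 12 were Ly86, S100a4, Stc2, Gmpr, Axl, Bahcc1, Cdsn, Vash1 and 2810025M15Rik. Both guides share the Y-linked pattern, so independence of the guides is not a sound baseline. The excess over 0.06 does not separate an effect of Phf6 from a shared origin of the KO lines. Of the 12, 10 stood at 5 CPM or more in KD. Against WT, 5 of the 12 were called lower and 5 higher in KD. The 9 that are not Y-linked lie on chromosomes 1, 3, 7, 11, 12, 13 and 17. Stc2, a secreted glycoprotein, had 8.68 CPM in WT and 69.6 in KD against 0 in KO_sg1, where a count of 0 allows up to 0.147 CPM in the smallest library, and 0.01 in KO_sg4. Vash1, a vasohibin, went from 8.24 CPM in WT to 0.12 in KO_sg1 and 0.081 in KO_sg4, with 6.42 in KD, and Cdsn, corneodesmosin, from 5.87 to 0.102 and 0.016, with 2.2 in KD.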
